A study of Mus musculus with 18 samples.

How the data were processed

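RNA from the cortex and striatum of 6-week-old control mice and mice carrying the TgCPEB4Δ4 transgene was measured on 18 single-colour Affymetrix arrays, 3 mice per genotype and 3 RNA preparations per mouse. Per the labels' protocols, total RNA was passed over poly(U)-agarose. A wash at 25% formamide released RNA enriched for short poly(A) tails and a wash at 90% formamide released RNA enriched for long tails. Per the labels' protocols, 5 ng of each RNA was amplified over 21 cycles, and 8 µg of the resulting cDNA was fragmented, labelled with biotin and hybridised. Amplification from 5 ng can compress or stretch differences between transcripts, and equal mass was labelled from each fraction, so the values give the share of a transcript within a fraction and not how much RNA a fraction held. The series design text names the array as Mouse PrimeView, whereas the probe set names and the annotation are those of a perfect-match array of another design. The latter annotation was used.

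The deposited values are log2 expression per probe set, made by the authors with RMA per the submitters' processing notes. RMA subtracts background, makes the intensity distributions of the arrays alike and summarises the probes of each probe set. Its version and whether all 18 arrays went into 1 run are not given in the sources used here. The deposited log2 values ran from 3.68 to 13.6. Because quantile normalization makes array distributions alike, a shift shared by most transcripts of a fraction cannot be seen in them. Arrays carry no read depth, and the number of mice limits the precision.

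The table held 45141 probe sets, of which 104 control probe sets were left out. Of the remaining 45037, the probe annotation gave 1 gene for 28898, several for 551 and no entry for 15588. Symbols were checked against the RefSeq gene table of assembly GRCm38.p6, which changed 0 of them. Probe sets with several genes or no entry were tested and counted, but not named. Probe sets were kept where the mean of the 18 arrays exceeded the 40th percentile, a log2 value of 5.95. That left 27022 probe sets, 19143 with 1 gene, 411 with several and 7468 without an entry. For counts of genes and for gene lists, each of 11974 genes was represented by the probe set with the highest mean. No array held the same values as another, and correlations between arrays ran from 0.645 to 0.995.

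The samples were grouped by the genotype and fraction in their labels, and mice by the number in their titles. Linear models were fitted with limma 3.58.1 in R 4.3.3 (statmod 1.5.0 for the random block), with Benjamini-Hochberg adjustment over all probe sets tested and two-sided adjusted p under 0.05 as the threshold. Total RNA, the short-tail fraction and the long-tail fraction were each compared between genotypes. For tail length, log2 of the long-tail value minus log2 of the short-tail value was taken within each mouse, here called the tail ratio. The mean tail ratio of each genotype was tested against 0, with all 6 mice sharing 1 estimate of the spread, and the difference between genotypes was tested in the same model. Where control mice varied more, as for Psmb7 (SD 2.1 against 0.15), this made tests too lenient in control and too strict in transgenic mice. The pairing of the fractions comes from the labels, which put them in 1 mouse. Deviations from group means correlated between the short-tail and long-tail arrays of a mouse at 0.72, 0.33 and 0.43 in transgenic mice and at -0.07, 0.16 and -0.03 in control mice. Where n was under 10 and a single value was compared, an exact two-sided permutation test was used, which cannot give a p below 0.1 for 3 mice against 3.

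Gene lists (33, of which 32 had measured members) covered autism-associated genes, neuronal groups, RNA classes, brain regions and cell types. They were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a comparison, and again with an estimated correlation and with fry. The median of a list was also ranked among 10000 random lists of the same size drawn within 20 bins of mean expression. The comparisons and their tests, the filter, the lists, the thresholds, the rule for naming genes and the alternatives for probe sets were set before the data were examined, except for the rescaling of each mouse's tail ratios to the same spread or slope. Camera was planned for total RNA and the genotype difference in tail ratio, with an estimated correlation, fry and the mean of all probe sets of a gene as alternatives, and the random lists for the same comparisons. Camera on the other comparisons, random lists in control mice and, for gene lists, the other filters, scalings and omissions of mice were added after the data were seen, as were tests of 3 lists joined into 1. These included random lists and an adjustment of their median tail ratio per mouse for 1 of 4 signs of array quality at a time, by a linear model with genotype. Sign flips over all 6 mice were added before their result was seen.

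Genes were named by rule. Up to 10 genes per direction were those with the largest difference among genes that passed with every mouse on one side. Where fewer than 5 passed, the 5 with the smallest unadjusted p in each direction were named and said not to pass. Cpeb1 to Cpeb4 and up to 4 members per list described, those with the smallest unadjusted p, were named in addition. Uncharacterised gene models were counted but not named.

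Each test was tested on simulated data with the mean of each probe set over all arrays and a spread averaged over the groups. In these data 100 of 27022 probe sets were changed by a log2 of 1 and 100 by a log2 of 2. Differences between fractions in level or spread, and the correlation between arrays of a mouse, were not simulated. At the smaller size, 49 were recovered in total RNA, 58 and 53 in the tail ratio of control and transgenic mice, 55 in the short-tail fraction and 42 in the long-tail fraction, but only 4 in the genotype difference of the tail ratio. At the larger size, 93, 94, 97, 94 and 94 were recovered in the same order, and 66 in the genotype difference of the tail ratio. Between 0 and 9 unchanged probe sets were called. These counts do not give the power of the real comparisons. In the real data the median SE between genotypes was 0.21 in the long-tail and 0.11 in the short-tail fraction. With 1 list shifted by -0.3, camera also called 2 unshifted lists in the genotype difference of the tail ratio. It called 1 in the short-tail fraction and 0 in the other comparisons.

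Alternatives were no filter or a 60th percentile filter, quantile normalization of all arrays again or within each fraction, centring of arrays on their medians, an intensity trend with robust moderation, array weights, an adjusted p under 0.10, 1 probe set per gene, each mouse left out in turn, models with and without a block, all 18 arrays in 1 model, and ratios to total RNA. A planned test of cytoplasmic polyadenylation elements in 3' untranslated regions was not run, because no genome sequence was used here.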

Results

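Transcript levels were measured in cortex and striatum, dissected together, from 3 control and 3 transgenic mice aged 6 weeks. The transgene, TgCPEB4Δ4, encodes a form of CPEB4 that lacks a microexon. CPEB4 belongs to a family of proteins that bind cytoplasmic polyadenylation elements in 3' untranslated regions and alter the length of the poly(A) tail. Each mouse gave 1 array of total RNA and 1 array of each fraction from a poly(U) column. RNA that left the column at 25% formamide was enriched for short tails, and RNA that left at 90% formamide for long tails. The median log2 value per array lay between 6.42 and 6.59 over the 18 arrays. The SD over all probe sets of an array was less alike. It was 1.70, 1.81 and 1.77 in the long-tail arrays of control mice and 1.85, 1.82 and 1.91 in those of transgenic mice. In short-tail arrays it ran from 1.94 to 2.00. In every array Xist, which is transcribed in females, stood at 9.22 or more, and the Y-linked Kdm5d, Eif2s3y and Uty stood at 5.36 or less.

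The fraction accounted for most of the variation between arrays, and the fractions of control mice stood on average further apart than those of transgenic mice. The first principal component held 61.6% of the variance. On it the long-tail arrays of control mice 1, 2 and 3 scored 140.3, 44.0 and 88.8, those of transgenic mice 31.8, 32.8 and -6.39, and all short-tail arrays between -60.6 and -45.8. The tail ratio is log2 of the long-tail over the short-tail value within a mouse. Its SD over all probe sets was 0.88 ± 0.30 in control and 0.54 ± 0.13 in transgenic mice (SD, n = 3). The genotypes overlapped in this measure (control 1.19, 0.593 and 0.859, transgenic 0.614, 0.621 and 0.388). An exact two-sided permutation test gave p = 0.3, with 0.1 the smallest it can give.

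**Figure D1:**
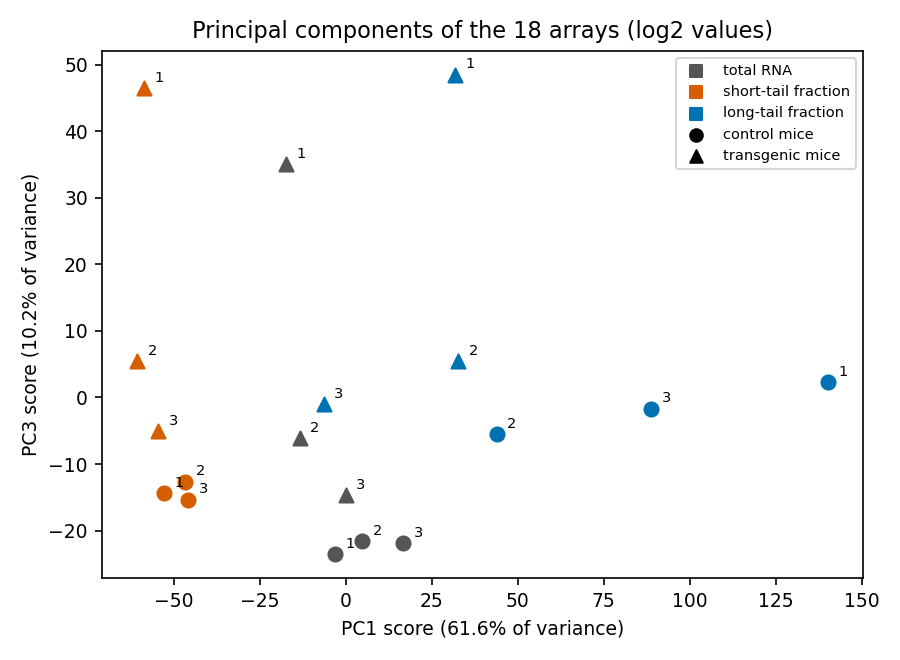
Scores of the 18 arrays on the first component (horizontal axis, 61.6% of the variance) and the third component (vertical axis, 10.2%), with colour for the RNA fraction, shape for the genotype and the number of each mouse beside its point. The long-tail array of control mouse 1 lies at 140.3 on the first component, and the 3 arrays of transgenic mouse 1 lie at 35.1, 46.5 and 48.5 on the third.

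No difference in Cpeb4 itself was detectable in total RNA. The probe set with the higher signal read 8.44, 8.36 and 8.30 in control and 8.58, 8.55 and 7.99 in transgenic mice, a log2 difference of 0.01 ± 0.16 (SE; adjusted p = 0.99, limma), and its sign turned when the arrays were quantile-normalized again (-0.07). A second Cpeb4 probe set differed by 0.27 (adjusted p = 0.64), with 0.03 to 0.51 without single mice. Neither probe set checks the genotype labels, because whether the transgene carries the sequence they read is not given in the sources used here. Cpeb1, Cpeb2 and Cpeb3 differed by 0.33, 0.10 and -0.14 in total RNA and did not pass (adjusted p = 0.57, 0.83 and 0.65).

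In total RNA no single transcript passed between the genotypes. Of 32 gene lists 14 passed with camera at its preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.56). Of 27022 probe sets, 0 passed in limma (lowest adjusted p = 0.36). At an unadjusted p under 0.05 there were 2935 against 1351 by chance, 1955 of them higher and 980 lower in transgenic mice. The genotypes did not overlap for 18.4% of probe sets, where chance gives 10%. None of the genes with the smallest p passed (adjusted p = 0.42 for each). Those that were higher were Ddit4, an inhibitor of mTORC1 (1.05 ± 0.17), the proteasome activator subunit Psme1 (0.91 ± 0.16), the cold-inducible RNA-binding protein Cirbp (1.51 ± 0.26), Ctxn2 (0.78 ± 0.14) and Zswim7 (0.72 ± 0.13; SE, n = 3). Those that were lower were the Ddit4 paralogue Ddit4l (-0.80 ± 0.14), the dense-core vesicle protein Ptprn2 (-0.59 ± 0.11), Mei1 (-0.48 ± 0.10), the striatal G protein regulator Rgs9 (-0.55 ± 0.12) and the active-zone protein Rims3 (-0.48 ± 0.11). On total RNA arrays Ddit4, Cirbp and Zswim7 stood above the highest nonspecific control on 0 of 3 control arrays, Rims3 on 0 of 3 and Ddit4l on 2 of 3 transgenic arrays and Mei1 on 0 of 3 of either, so these differences are not exact values.

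Of the 14 lists that passed in total RNA 8 ranked upward and 6 downward, and with fry none passed (lowest adjusted p = 0.11). An exact two-sided permutation test on the list median of each mouse, which cannot give less than 0.1, gave p = 0.1 for meningeal, microglial and ribosomal protein lists and p = 0.2 for endothelial, proteasome and oligodendrocyte lists. The same exact test gave p = 0.3 for astrocyte and striatal lists, 0.5 for the glutamatergic postsynapse and 0.9 for voltage-gated channels. The 13 measured meningeal and fibroblast genes were all higher in transgenic mice, with a median of 0.64 (adjusted p = 5.1e-08). The list had adjusted p = 0.57 with an estimated correlation. Over all genes 0 of them passed, and 9 did when adjusted over the list alone. Islr differed by 1.34 ± 0.26, Mgp by 0.72 ± 0.20, Slc6a13 by 0.58 ± 0.16 and Col1a1 by 0.47 ± 0.11. Islr stood above the highest nonspecific control on 0 of 3 control and 1 of 3 transgenic arrays and Slc6a13 on 1 of 3 control arrays, so their differences are not exact values. Of 23 astrocyte markers 22 were higher, with a median of 0.32 (adjusted p = 7.8e-06), and adjusted p = 0.57 with an estimated correlation. Among them were the mitochondrial glutamate carrier Slc25a18 (0.89 ± 0.19) and Aldh1l1 (0.72 ± 0.22). Microglial markers had a median of 0.46 with 16 of 19 higher (adjusted p = 9.1e-05), and endothelial and mural markers 0.18 with 20 of 22 higher (adjusted p = 0.00091). Each had adjusted p = 0.57 with an estimated correlation. Adjusted over the list alone, 1 astrocyte, 0 microglial and 0 endothelial genes passed.

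Ribosomal protein mRNAs were higher by a median of 0.20, with 65 of 66 above 0 (adjusted p = 3.2e-10), and proteasome mRNAs by 0.18, with 29 of 30 above 0 (adjusted p = 7.8e-06). They had adjusted p = 0.57 and 0.56 with an estimated correlation. Striatal markers had a median of -0.14 with 22 of 27 lower (adjusted p = 8.6e-07; adjusted p = 0.56 with an estimated correlation). In this list 0 genes passed over all genes and 4 when adjusted over the list alone. Scn4b (-0.63 ± 0.15), Ryr1 (-0.63 ± 0.16), Rgs9 (-0.55 ± 0.12) and Pde10a (-0.37 ± 0.10) had the smallest p, Scn4b with 1 of 3 transgenic arrays above the highest nonspecific control. Genes of the glutamatergic postsynapse had a median of -0.12 with 38 of 46 lower, among them Homer1 (-0.59 ± 0.19) and Cacng3 (-0.45 ± 0.13; adjusted p = 3.2e-05). Voltage-gated channels had a median of -0.14 with 30 of 38 lower, among them Kcna4 (-0.42 ± 0.13; adjusted p = 4e-05). The channel medians of the mice were 9.45, 9.38 and 9.38 in control and 8.97, 9.46 and 9.40 in transgenic mice, so that only transgenic mouse 1 lay below the controls. Both lists had adjusted p = 0.57 with an estimated correlation. In both, and in the ribosomal and proteasome lists, 0 genes passed over all genes and 0 when adjusted over the list alone. Without transgenic mouse 1 the medians were 0.11 for ribosomal proteins, -0.06 for the glutamatergic postsynapse and -0.05 for voltage-gated channels, and these lists still passed (adjusted p = 3.7e-05, 0.0049 and 0.017). Oligodendrocyte markers (-0.10, adjusted p = 0.0043) also ranked lower, with adjusted p = 0.57 with an estimated correlation. The calls for presynaptic genes (-0.09, adjusted p = 0.01) and activity-regulated genes (-0.15, adjusted p = 0.043) ended without transgenic mouse 1 (0.00 and -0.02, adjusted p = 0.33 and 0.14) and without control mouse 1 (-0.05 and -0.12, adjusted p = 0.11 and 0.19). That for activity-regulated genes also ended without control mouse 2 (-0.11, adjusted p = 0.082), and its median was -0.28 without transgenic mouse 3. The call for oxidative phosphorylation (0.07, adjusted p = 0.04) ended without control mouse 3, transgenic mouse 2 or transgenic mouse 3 (0.05, 0.06 and 0.06, adjusted p = 0.20, 0.11 and 0.28). With an estimated correlation these 3 had adjusted p = 0.67, 0.57 and 0.67. Autism-associated genes did not pass with camera, with a median of -0.01 over 92 genes, 42 higher and 50 lower (adjusted p = 0.19). Among random lists of the same expression this median ranked low, at percentile 0.24, below the range of 0.01 to 0.09 that held most of them. Random lists do not account for correlation between genes.

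Transgenic mouse 1 differed from the other 5 mice in genes of inflammation and the interferon response, in all 3 of its RNA preparations. Of the 18 measured members of the list 14 were highest in this mouse in total RNA, 16 in the short-tail and 14 in the long-tail fraction. In total RNA the other 4, Ccl2, Irf1, Il1b and Tnf, stood above the highest nonspecific control in none of the 6 mice. In total RNA the acute-phase protein Lcn2 stood at 10.8 in this mouse against 5.20 to 5.48 in the others. The protease inhibitor Serpina3n stood at 11.8 against 5.93 to 8.64, the complement component C4b at 11.2 against 7.45 to 9.78, and the antiviral proteins Rsad2 and Oasl2 at 8.83 and 7.78 against 6.21 to 6.52 and 5.18 to 5.89. The astrocyte filament Gfap stood at 12.7 against 10.5 to 12.2. In total RNA Serpina3n stood above the highest nonspecific control probe set on 0 of 3 control and 2 of 3 transgenic arrays. Lcn2, Rsad2 and Oasl2 stood above it in this mouse alone. Values of these genes that did not exceed that control are not exact levels. This mouse and these genes were singled out after their values were seen. With it, the 18 measured genes of the inflammation and interferon list had a median difference of 0.76 in total RNA (adjusted p = 0.0075; adjusted p = 0.66 with an estimated correlation). Without it the median was 0.19 and the list did not pass (adjusted p = 0.083), nor did it pass without control mouse 1 (0.72, adjusted p = 0.11). Without transgenic mouse 1 the astrocyte, microglial and meningeal medians were 0.17, 0.29 and 0.49.

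**Figure D2:**
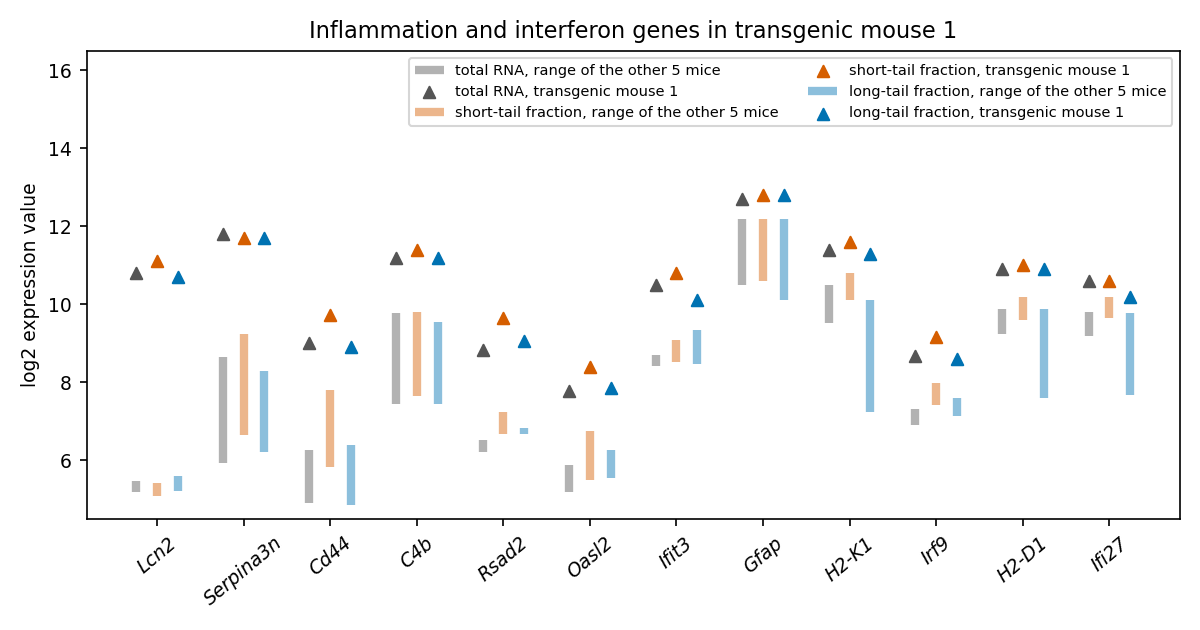
Log2 expression value (vertical axis) of 12 of the 18 genes of the inflammation and interferon list, those over 1 above the mean of the other mice in total RNA, in transgenic mouse 1 (triangles) and the range of the other 5 mice (bars), for total RNA, the short-tail and the long-tail fraction. Lcn2 reads 10.8, 11.1 and 10.7 in transgenic mouse 1 and at most 5.61 in any other mouse.

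In control mice most probe sets lay toward one of the fractions. Some mRNAs of postsynaptic, channel and chromatin proteins lay toward the long-tail fraction and fewer of them toward the short-tail fraction. Nearly all mRNAs of ribosomal proteins, the respiratory chain and the proteasome lay toward the short-tail fraction. With limma 17034 of 27022 probe sets passed, 7465 with a positive and 9569 with a negative tail ratio, or 2457 and 4772 of 11974 genes. Of the probe sets passing 43.8% were positive, against 53.2% with quantile normalization again, 56.5% without a filter and 34.1% with centring, so the direction of the majority depended on the scaling and filter. The largest positive tail ratios were those of the antisense RNA Kcnq1ot1 (1.83 ± 0.39, SD, n = 3), Rgs9 (1.83 ± 0.36), Srrm4os (1.81 ± 0.91), Fam53b (1.75 ± 0.77), the chromatin reader Zmynd8 (1.69 ± 0.27), Lrtm1 (1.69 ± 0.19), the keratin Krt20 (1.65 ± 0.25), Tma16 (1.63 ± 0.85), the actin-binding adaptor Sorbs2 (1.63 ± 0.33) and Ankrd52 (1.62 ± 0.73), with adjusted p from 0.00045 to 0.0028. The largest negative ones were those of the proteasome subunits Psmb7 (-4.15 ± 2.1) and Psma6 (-3.20 ± 1.7), the respiratory chain subunits Uqcrb (-4.06 ± 1.7), Ndufb5 (-3.26 ± 0.84), Ndufc1 (-3.10 ± 1.0) and Ndufa1 (-3.06 ± 1.1), the small nucleolar ribonucleoprotein Nhp2 (-3.12 ± 0.40), the host gene of small nucleolar RNAs Snhg8 (-3.11 ± 1.2), the ribosomal protein Rpl39 (-3.07 ± 1.2) and Ranbp6 (-3.04 ± 1.3), with adjusted p from 0.00045 to 0.0013. In the long-tail fraction of control mice Psmb7, Uqcrb, Nhp2 and Ranbp6 stood above the highest nonspecific control on 1 of 3 arrays and Psma6, Ndufb5 and Rpl39 on 2, and Fam53b on 2 of 3 short-tail arrays, so their tail ratios are not exact values. Of the 3 tested probe sets of Zmynd8, 2 had a positive tail ratio and 1 passed. By the probe set with the higher signal, Cpeb3 lay toward long tails (0.75 ± 0.21, adjusted p = 0.0031) and Cpeb1 (-0.52 ± 0.13), Cpeb2 (-0.96 ± 0.22) and Cpeb4 (-0.98 ± 0.59) toward short tails (adjusted p = 0.025, 0.011 and 0.0046). Cpeb1 did not pass without any 1 of the control mice (adjusted p = 0.058, 0.065 and 0.058) or with quantile normalization again (0.062), and Cpeb4 read -0.64 without control mouse 1. A second probe set of Cpeb3 did not pass and had the opposite sign (-0.18 ± 0.62, adjusted p = 0.49), and those of Cpeb2 (-0.98 ± 0.48) and Cpeb4 (-2.10 ± 1.2) lay toward short tails (adjusted p = 0.0063 and 0.004), the latter -1.39 without control mouse 1. In the long-tail fraction of control mice both Cpeb2 probe sets stood above the highest nonspecific control on 1 of 3 arrays, and Cpeb1 and both Cpeb4 probe sets on 2.

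Of 66 ribosomal protein mRNAs 64 lay toward short tails in control mice and 0 toward long tails, or 66 when adjusted over the list alone, with a median tail ratio of -1.66 (camera adjusted p = 5e-14). Of 69 nuclear-encoded mRNAs of oxidative phosphorylation 68 lay toward short tails, or 69 adjusted over the list alone, with a median of -1.97 (adjusted p = 5e-16). All 30 proteasome mRNAs did, also when adjusted over the list alone, with a median of -1.79 (adjusted p = 2.8e-07). Each of the 3 lists had adjusted p = 0.74 with an estimated correlation, and with fry they passed (adjusted p = 0.0067, 0.0067 and 0.014). Rpl31 read -2.03 ± 0.27, Rps10 -1.59 ± 0.28, Ndufb7 -2.09 ± 0.20, Atp5g1 -1.70 ± 0.31, Psmb1 -2.60 ± 0.84 and Psmb6 -2.58 ± 0.73. Psmb1 and, among oligodendrocyte markers, Ppp1r14a and Ermn stood above the highest nonspecific control on 2 of 3 control long-tail arrays. Oligodendrocyte markers had a median of -0.64, with 0 toward long and 16 of 26 toward short tails (16 adjusted over the list alone), among them Ppp1r14a (-1.70 ± 0.34) and Ermn (-1.08 ± 0.19). This median lay inside the range of -0.71 to 0.02 that held most random lists of the same expression, at percentile 4.73. The camera adjusted p was 0.027, with adjusted p = 0.74 with an estimated correlation, and this call ended without control mouse 1 or 3 (-0.49 and -0.63, adjusted p = 0.053 and 0.062), and with the 60th percentile filter or quantile normalization again (adjusted p = 0.075 and 0.081).

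Autism-associated mRNAs leaned toward long tails in control mice, with 34 of 92 toward long and 20 toward short tails (34 and 20 adjusted over the list alone) and a median of 0.17 (adjusted p = 0.004). The list had adjusted p = 0.74 with an estimated correlation and did not pass with fry (adjusted p = 0.066). Nlgn1, a synaptic adhesion protein, read 1.46 ± 0.43, Ubn2 1.39 ± 0.39, the growth regulator Tsc1 1.19 ± 0.16 and the cohesin loader Nipbl 1.05 ± 0.35. Voltage-gated channels had a median of 0.30, with 16 of 38 toward long and 10 toward short tails (16 and 10 adjusted over the list alone; adjusted p = 0.0097; adjusted p = 0.74 with an estimated correlation). Kcnh7 (1.48 ± 0.64), Kcnj6 (1.28 ± 0.26) and Cacna1e (1.27 ± 0.39) lay toward long tails and Cacnb4 (-1.21 ± 0.49) toward short tails. Chromatin regulators had a median of 0.15, with 19 of 51 toward long and 10 toward short tails (18 and 10 adjusted over the list alone; adjusted p = 0.0097; adjusted p = 0.74 with an estimated correlation). They were led by Chd7 (1.39 ± 0.62), Baz2b (1.26 ± 0.38) and Bptf (1.18 ± 0.48), and their call ended without control mouse 3 (0.13, adjusted p = 0.065). Genes of the glutamatergic postsynapse had a median of 0.19, with 17 of 46 toward long and 7 toward short tails (16 and 6 adjusted over the list alone; adjusted p = 0.0097; adjusted p = 0.74 with an estimated correlation). Presynaptic genes did not pass, with a median of -0.22, 11 of 42 toward long and 13 toward short tails (adjusted p = 0.75). The presynaptic scaffold Bsn read 1.43 ± 0.48 and the postsynaptic adhesion protein Lrrtm1 -2.49 ± 1.1. Lrrtm1 and Cacnb4 stood above the highest nonspecific control on 2 of 3 control long-tail arrays. None of the camera calls in any comparison held with an estimated correlation. With fry, which tests a list against no change, 20 of 32 lists passed in control mice. Oligodendrocyte markers, channels and the postsynapse were among them (fry adjusted p = 0.013, 0.026 and 0.044), and chromatin regulators were not (0.08). Without control mouse 2 the medians of channels, chromatin regulators and the glutamatergic postsynapse were 0.50, 0.25 and 0.31, and without control mouse 1 that of the postsynapse was 0.13. Without the filter on low signal these 4 lists did not pass (adjusted p = 0.2 for the autism-associated list and 0.16 for the others).

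Transgenic mice showed a largely similar arrangement with fewer probe sets passing. With limma 8601 probe sets passed, 3441 with a positive and 5160 with a negative tail ratio, or 778 and 2452 genes. With each genotype fitted alone and arrays taken as independent, 14137 passed in control and 9594 in transgenic mice, so the gap depended on the model. Voltage-gated channels did not pass with camera in transgenic mice (median 0.07, adjusted p = 0.063). Chromatin regulators passed (adjusted p = 0.027) but with a median of -0.05, 25 higher and 26 lower. Positive tail ratios were led by Lrtm1 (1.40 ± 0.53), Zmynd8 (1.31 ± 0.30), Kcnq1ot1 (1.31 ± 0.36), Zfp248 (1.29 ± 0.57), Ccdc30 (1.23 ± 0.18), Sorbs2 (1.18 ± 0.16), Krt20 (1.18 ± 0.15), Fnbp1 (1.13 ± 0.29), Nlgn1 (1.12 ± 0.31) and the ubiquitin ligase Herc4 (1.11 ± 0.19), with adjusted p from 0.0035 to 0.0075. Negative ones were led by the calcium-binding protein S100a6 (-1.99 ± 0.45), Iftap (-1.87 ± 0.33), Tmem167 (-1.86 ± 0.48), Ctxn2 (-1.85 ± 0.55), Rpl22l1 (-1.83 ± 0.26), the peroxiredoxin Prdx4 (-1.83 ± 0.35), Gmfb (-1.81 ± 0.25), the neuropeptide gene Crh (-1.77 ± 0.75), the purine enzyme Pnp (-1.76 ± 0.47) and Nhp2 (-1.75 ± 0.37), with adjusted p from 0.0028 to 0.0048. Prdx4 and Crh stood above the highest nonspecific control on 1 of 3 long-tail arrays of transgenic mice and S100a6 and Rpl22l1 on 2, and Zfp248 and Nlgn1 on 2 of 3 short-tail arrays. Of the 2 tested probe sets of Herc4, 1 had a positive tail ratio, and of the 3 of Zfp248, 2 had. Cpeb2 (-1.07 ± 0.76, adjusted p = 0.017) and Cpeb4 (-0.87 ± 0.17, adjusted p = 0.018) lay toward short tails, and Cpeb1 (-0.33 ± 0.42) and Cpeb3 (0.34 ± 0.25) did not pass (adjusted p = 0.15 and 0.10). The second probe sets read -0.69 ± 0.48 for Cpeb2 (adjusted p = 0.047), -0.175 ± 0.21 for Cpeb3 and -1.15 ± 0.80 for Cpeb4, the latter 2 not passing (adjusted p = 0.55 and 0.072). Both Cpeb2 probe sets stood above the highest nonspecific control on 1 of 3 long-tail arrays. The call for the second Cpeb2 probe set ended without transgenic mouse 1 or 2 or control mouse 3 (adjusted p = 0.19, 0.31 and 0.064). The call for Cpeb4 also ended without transgenic mouse 3 (-0.92, adjusted p = 0.052). In limma 0 probe sets passed without transgenic mouse 1 or 2 (lowest adjusted p = 0.0568 and 0.0557, with 7404 and 6880 at an unadjusted p under 0.05). Without control mouse 1, which shares the estimate of the spread, 13560 passed. Quantile normalization of all arrays again left 4986 probe sets, 55.5% of them positive against 40% as deposited, and centring on array medians gave 29%.

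In transgenic mice 33 of 66 ribosomal protein mRNAs, 45 of 69 mRNAs of oxidative phosphorylation and 9 of 30 proteasome mRNAs lay toward short tails (37, 51 and 8 adjusted over the list alone) and 0 toward long tails. The medians were -0.68, -0.83 and -0.64 (camera adjusted p = 2e-06, 9.2e-09 and 0.014; adjusted p = 0.94 for each with an estimated correlation). With fry none of these lists passed (adjusted p = 0.065, 0.053 and 0.14), whereas 11 of the 32 lists did. Microglial markers had a median of -0.45, with 0 toward long and 8 of 19 toward short tails (9 adjusted over the list alone), among them Tyrobp (-1.50 ± 0.26) and C1qa (-1.22 ± 0.36; adjusted p = 0.014; adjusted p = 0.94 with an estimated correlation). Nuclear long noncoding RNAs had a median of 0.31, with 5 of 14 toward long and 2 toward short tails (5 and 2 adjusted over the list alone; adjusted p = 0.014; adjusted p = 0.94 with an estimated correlation). Malat1 (0.58 ± 0.27) and Miat (0.58 ± 0.14) lay toward the long-tail fraction and Pantr1 (-1.25 ± 0.22) toward the short-tail fraction. A place in the long-tail fraction does not by itself show that such an RNA carries a long tail. Autism-associated genes had a median of 0.03, with 10 of 92 toward long and 5 toward short tails (7 and 3 adjusted over the list alone; adjusted p = 0.014; adjusted p = 0.94 with an estimated correlation). With fry the autism-associated list did not pass (adjusted p = 0.48). Its median was 0.02 without transgenic mouse 1 and 0.07 without transgenic mouse 3. The sign of this median turned after centring on array medians (-0.05) and after normalization within each fraction (-0.01). Scaling also moved the median tail ratio of all probe sets. It went from -0.07 to 0.08 in control and from -0.11 to 0.01 in transgenic mice with quantile normalization again, and to -0.19 in control mice with centring, so positive and negative tail ratios are relative to these medians.

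**Figure D3:**
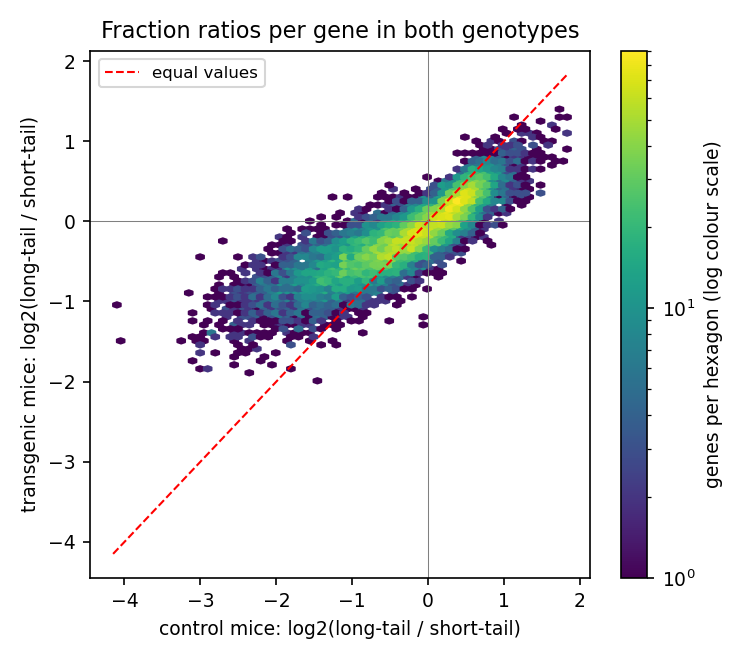
Mean tail ratio per gene in control mice (horizontal axis) and transgenic mice (vertical axis), both as log2 of the long-tail over the short-tail value, for 11974 genes, with colour for the number of genes per hexagon on a log scale and a dashed line at equal values. Signs were the same for 87.3% of genes, and the slope across genes was 0.487.

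The main question of the series was whether the spread of transcripts between the fractions differed by genotype. The order of genes was largely shared. The slope of transgenic on control tail ratios was below 1, but the SD of the tail ratio per mouse overlapped between genotypes (exact permutation p = 0.3). Across 11974 genes, which are not independent replicates, tail ratios of the genotypes correlated at Pearson r = 0.863 with a slope of 0.487 of transgenic on control, and 87.3% had the same sign. Of 7229 genes that passed in control and 3230 in transgenic mice 2949 passed in both, all with the same sign. Of these 738 were positive and 2211 negative, where independent lists would share 160 and 977. Both tests used the same estimate of the spread, so the lists were not independent and these numbers are only a rough reference. For single genes, 0 of 27022 probe sets passed in the test of the difference (limma, lowest adjusted p = 0.37). At an unadjusted p under 0.05 there were 3621 against 1351 by chance, 2413 higher and 1208 lower in transgenic mice. The genotypes did not overlap for 18.2%, where chance gives 10%. Without control mouse 2, whose fractions stood closest together among the controls, 2487 probe sets passed.

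The smallest p toward higher tail ratios in transgenic mice belonged to the respiratory chain subunit Ndufb7 (-2.09 ± 0.20 in control and -0.92 ± 0.05 in transgenic mice, SD, n = 3), the microglial adaptor Tyrobp (-2.94 ± 0.41 and -1.50 ± 0.26), Rpl31 (-2.03 ± 0.27 and -0.70 ± 0.36), the mitochondrial ribosomal protein Mrpl13 (-2.21 ± 0.38 and -1.02 ± 0.12) and Nhp2 (-3.12 ± 0.40 and -1.75 ± 0.37). Toward lower tail ratios it belonged to the potassium channel Kcnq3 (0.87 ± 0.30 and -0.03 ± 0.07), the receptor Gpr173 (0.71 ± 0.35 and -0.22 ± 0.20), Mia (-0.08 ± 0.33 and -1.30 ± 0.54), the protease inhibitor A2m (0.37 ± 0.13 and -0.40 ± 0.22) and Tmem212 (-0.04 ± 0.05 and -1.18 ± 0.61). None of these 10 genes passed (limma adjusted p = 0.37 for each). In the long-tail fraction of control mice Tyrobp, Nhp2 and Tmem212 stood above the highest nonspecific control on 1 of 3 arrays, and Mrpl13, Mia and A2m on 2, so their differences are not exact values. Cpeb1, Cpeb2, Cpeb3 and Cpeb4 differed by 0.19, -0.12, -0.41 and 0.11 and did not pass (adjusted p = 0.71, 0.88, 0.39 and 0.86). Second probe sets of Cpeb2, Cpeb3 and Cpeb4 differed by 0.29 ± 0.32, 0.00 ± 0.31 and 0.95 ± 0.61 (SE) and did not pass (adjusted p = 0.66, 1 and 0.47). Without control mouse 1 they were 0.01, -0.33 and 0.24. With the probe set of higher signal, the sign for Cpeb2 turned with quantile normalization again (0.03) and that for Cpeb4 after rescaling (-0.34).

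By list, 8 of 32 passed with camera, 4 higher and 4 lower in transgenic mice, and with an estimated correlation or fry 0 passed (lowest adjusted p = 0.72 and 0.40). The median tail ratio of ribosomal protein mRNAs was higher by 1.02, with 65 of 66 above 0 (camera adjusted p = 6.9e-24). That of oxidative phosphorylation was higher by 1.12, with 69 of 69 above 0 (adjusted p = 1.8e-28), and that of the proteasome by 1.18, with 30 of 30 above 0 (adjusted p = 1e-12). Each had adjusted p = 0.72 with an estimated correlation. Over all genes 0 members passed, and when adjusted over the list alone 50, 62 and 22 did. Rpl12 differed by 1.87 ± 0.41, Ndufv3 by 1.77 ± 0.38, Ndufb5 by 1.74 ± 0.39 and Psmb7 by 3.11 ± 0.86 (SE). On control long-tail arrays Psmb7 stood above the highest nonspecific control on 1 of 3 and Ndufb5 and Rpl12 on 2, so their differences are not exact values. Taken per mouse, the median of the 3 lists together was -2.09, -1.10 and -2.21 in control and -0.73, -0.77 and -0.62 in transgenic mice, without overlap, and the exact two-sided permutation p was 0.1, the smallest possible. These are the lists with the lowest tail ratios in control mice, and the fractions of transgenic mice also stood on average closer together over all probe sets. After each mouse was rescaled to the same slope, the medians of the lists differed by 0.47, 0.48 and 0.47 and still passed (adjusted p = 1e-08, 2.7e-13 and 1e-08).

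The lists that leaned toward long tails in control mice ranked lower in transgenic mice by camera. Taken per mouse, the genotypes overlapped in each of them, and the exact two-sided permutation p was 0.2 for autism-associated genes, channels and the postsynapse and 0.3 for chromatin regulators. Autism-associated genes differed by a median of -0.13, with 63 of 92 lower (adjusted p = 0.011; adjusted p = 0.72 with an estimated correlation). Kcnq3 (-0.90 ± 0.20) and Ubn2 (-0.75 ± 0.25) were lower, and Cep41 (0.63 ± 0.17) and Snd1 (1.21 ± 0.48) higher. Voltage-gated channels differed by -0.25 with 24 of 38 lower (Kcnh7 -1.10 ± 0.33, Hcn2 -0.82 ± 0.29; adjusted p = 0.0081). Chromatin regulators differed by -0.16 with 33 of 51 lower (Baz2b -0.60 ± 0.24, but Hdac2 2.58 ± 0.96; adjusted p = 0.016), and genes of the glutamatergic postsynapse by -0.12 with 31 of 46 lower (Grin2a -0.80 ± 0.30, Grik5 -0.75 ± 0.23; adjusted p = 0.016). These 3 lists had adjusted p = 0.72 with an estimated correlation. In these 4 lists 0 members passed over all genes or adjusted over the list alone. Cep41 and Hdac2 stood above the highest nonspecific control on 2 of 3 control long-tail arrays and Grin2a on 2 of 3 transgenic short-tail arrays. Oligodendrocyte markers were higher by 0.36 with 20 of 26 above 0 (adjusted p = 0.016; adjusted p = 0.72 with an estimated correlation), 0 of them passing by either adjustment. In the order given, these 5 calls ended without control mouse 3 (medians -0.07, -0.19, -0.07, -0.13 and 0.30, adjusted p = 0.24, 0.082, 0.35, 0.14 and 0.085). Those for chromatin regulators and the postsynapse also ended without transgenic mouse 2 (-0.10 and -0.13, adjusted p = 0.059 and 0.057). Chromatin regulators read -0.27 without control mouse 2 and the glutamatergic postsynapse -0.19 without transgenic mouse 1. All 5 also ended after rescaling to the same slope (0.03, -0.01, 0.04, 0.01 and 0.24, adjusted p = 0.81, 0.23, 0.81, 0.81 and 0.42).

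**Figure D4:**
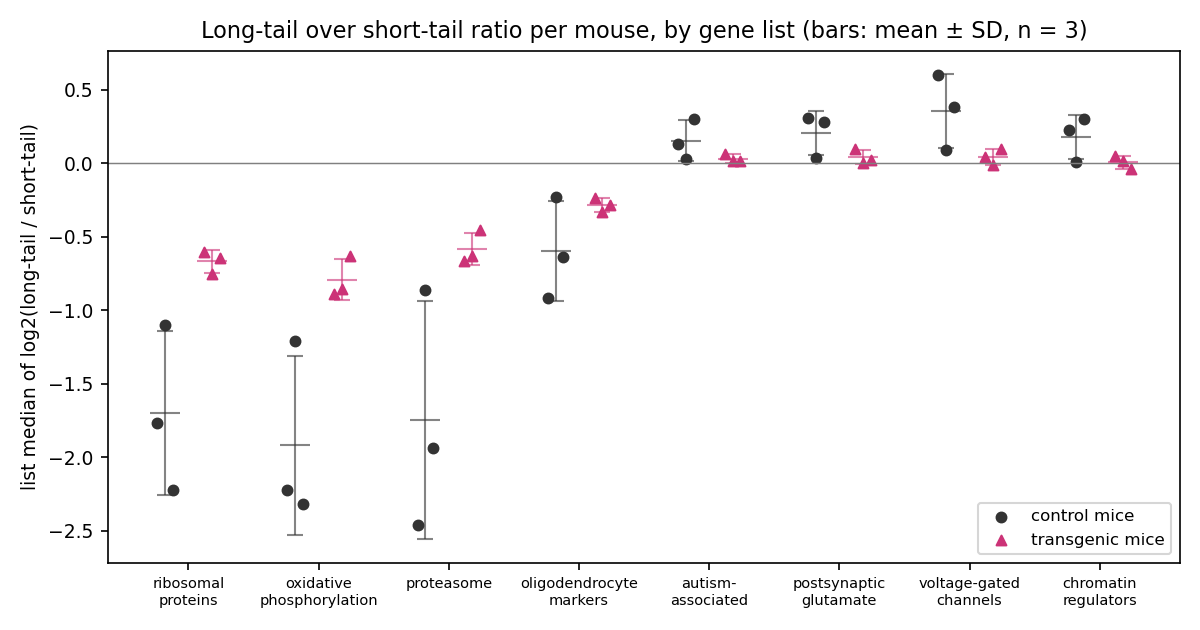
Median tail ratio of 8 gene lists (vertical axis, log2 of the long-tail over the short-tail value) in each control mouse (circles) and transgenic mouse (triangles), with horizontal bars for the mean and SD of 3 mice. For ribosomal proteins and oxidative phosphorylation all transgenic mice lie nearer 0 than all control mice, and for autism-associated genes the ranges overlap.

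The short-tail lists passed between genotypes in the long-tail fraction and not in the short-tail fraction. In the former ribosomal protein, oxidative phosphorylation and proteasome mRNAs were higher in transgenic mice by medians of 1.07, 1.09 and 1.18 (camera adjusted p = 3.1e-22, 1.6e-20 and 3e-11; adjusted p = 0.59, 0.66 and 0.66 with an estimated correlation), and in the short-tail fraction by 0.06, 0.01 and 0.04 (adjusted p = 0.14, 0.59 and 0.40). The long-tail arrays of control mice 1 and 3, the mice with the lowest tail ratios of these lists, also differed in control probe sets. Their actin 3' minus 5' signals were -1.08 and -0.958 against -0.745 to -0.662 in the other 4 long-tail arrays, and those of pyruvate carboxylase 0.841 and 0.573 against 0.0253 to 0.503. In the array of control mouse 1 the GAPDH difference was 0.151 against -0.179 to -0.115 in the others, and 16004 probe sets stood above the highest nonspecific control against 24511 to 31233. Single genes did not pass in either fraction. In the long-tail fraction 0 probe sets passed (limma, lowest adjusted p = 0.28) and 4454 had an unadjusted p under 0.05, 3249 higher and 1205 lower. Tyrobp (2.16 ± 0.27), the lectin Lgals1 (1.45 ± 0.21), Psmg4 (1.13 ± 0.19), Rps26 (0.95 ± 0.17) and the myelin protein Pmp22 (1.34 ± 0.24) had the smallest p upward. Cdr1os (-1.16 ± 0.19), Mical2 (-0.99 ± 0.22), Krt20 (-0.81 ± 0.18), the activin subunit Inhba (-1.01 ± 0.23) and Rgs9 (-0.97 ± 0.23) had the smallest p downward (adjusted p = 0.28 for each). The differences of Tyrobp, Psmg4 and Pmp22 are not exact values, because they stood above the highest nonspecific control on 1, 2 and 2 of 3 control arrays. In the short-tail fraction 0 probe sets passed (lowest adjusted p = 0.0609) and 4466 had an unadjusted p under 0.05, 2752 higher and 1714 lower. There the cornified envelope protein Lor (1.06 ± 0.10), Dlk1 (1.15 ± 0.16), Ctxn2 (0.62 ± 0.09), Ttc28 (0.78 ± 0.11) and the copper transporter Slc31a1 (0.61 ± 0.09) had the smallest p upward. Ddit4l (-0.89 ± 0.10), the sodium channel subunit Scn4b (-0.68 ± 0.10), Ptprn2 (-0.46 ± 0.08), Kcnj1 (-0.47 ± 0.08) and Vgll1 (-0.47 ± 0.09) had the smallest p downward (adjusted p from 0.061 to 0.16). The genotypes did not overlap for 24.5% and 24.6% of probe sets in the long-tail and short-tail fraction, where chance gives 10%.

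Meningeal, microglial and astrocyte markers were higher in transgenic mice in both fractions as in total RNA, as ranked by camera. The medians were 0.75, 0.49 and 0.46 in the long-tail fraction (adjusted p = 3.6e-06, 0.00094 and 0.00041; adjusted p = 0.59, 0.66 and 0.66 with an estimated correlation). They were 0.81, 0.42 and 0.30 in the short-tail fraction (adjusted p = 1e-09, 9.5e-05 and 9.5e-05; adjusted p = 0.76, 0.76 and 0.80 with an estimated correlation). Transgenic mouse 1, which had the high inflammation and interferon genes, had the highest meningeal median in all 3 preparations. It was 8.68, 9.08 and 8.72 in total RNA, the short-tail and the long-tail fraction, against at most 7.58, 7.90 and 7.78 in control mice. Without transgenic mouse 1 the microglial and astrocyte medians of the short-tail fraction were both 0.19 and still passed (adjusted p = 0.00067 and 0.0076). Leaving out single mice changed the counts of passing probe sets. They became 2319 in the long-tail fraction without control mouse 2, and 10 and 359 in the short-tail fraction without transgenic mouse 1 and 3. With all 18 arrays in 1 model, 4677 probe sets passed in the long-tail fraction. That model shares 1 spread over the preparations. Fitted alone, the long-tail fraction had a median SE of 0.21, against 0.11 in the short-tail fraction and 0.13 in total RNA. The shared spread therefore understates the error of the long-tail fraction.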

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

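The tests on other splits of the genotypes, on rescaled tail ratios, on random lists, on single mice, on array quality and on the arrays of transgenic mouse 1 were chosen only after the results were seen, and those on the fractions before. In the tail ratio, 8 gene lists differed between control and transgenic mice by camera at its preset correlation, and none did with an estimated correlation. The median differences were 1.02 for ribosomal proteins, 1.12 for oxidative phosphorylation, 1.18 for the proteasome, 0.363 for oligodendrocyte markers, -0.132 for autism-associated genes, -0.119 for the glutamatergic postsynapse, -0.248 for voltage-gated channels and -0.161 for chromatin regulators.

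The first pattern is the higher tail ratio of ribosomal, oxidative phosphorylation and proteasome mRNAs in transgenic mice. A trend with expression level is argued against, because the median shift of the 3 lists together, 1.10, lay at percentile 100 of random lists of the same expression, whose highest was 0.478. A single control mouse is argued against as well, since the shift was 0.955, 1.46 and 0.88 without control mouse 1, 2 and 3. Control mice 1 and 3 together are not addressed, because leaving out 1 mouse keeps the other. Their medians were -2.09 and -2.21, against -1.10 in control mouse 2. Weaker separation of the fractions in the transgenic preparations cannot be told apart from an effect of the transgene, because after rescaling to the same slope the shift was 0.479 (control -1.28 ± 0.29, transgenic -0.793 ± 0.24), and the lowest transgenic mouse stood only 0.0406 above the highest control mouse, within the spread. Array or RNA quality cannot be told apart as part of the difference of 1.09 ± 0.35 (SE, 6 mice), which was 0.641 ± 0.18 after adjustment for the actin 3' minus 5' signal of the long-tail arrays, with the genotypes 0.442 apart against a control SD of 0.23, and 0.845 to 0.95 after adjustment for 3 other signs of quality, with the genotypes as little as 0.26 apart against a control SD of 0.33. The SD of the values within a long-tail array, lower in every control mouse than in every transgenic mouse, was not among the signs adjusted for.

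The second pattern is the lower tail ratio of autism-associated mRNAs in transgenic mice. After rescaling to the same slope the median difference went from -0.132 to 0.0314 and the list did not pass (adjusted p = 0.81, with 0.00016 to 0.81 over all alternatives). Weaker separation of the fractions is therefore a candidate explanation. An effect of the transgene stays open, since the separation itself may differ by genotype and rescaling would remove such a difference too.

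The third pattern is the high level of inflammation and interferon genes in transgenic mouse 1. A fault of a single array is argued against, because 3 of its 3 arrays had the highest list median of all mice. More meningeal tissue in the dissection cannot be told apart from a state of this mouse. Transgenic mouse 2 had 84.8%, 56.3% and 60.1% of the rise of mouse 1 over the control mean in the meningeal median, and 12.8%, 39.1% and 11.9% of its rise in the interferon median, in total RNA, the short-tail and the long-tail fraction. An infection, an injury or another state of this mouse may underlie the pattern, and none of these was tested.

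Splits of 3 mice against 3 are too few for a share under 0.05. Between genotypes 10 of 10 splits gave as many passing probe sets in limma, in total RNA, the tail ratio, the short-tail and the long-tail fraction, since the real value and the highest other were 0. At an unadjusted p under 0.05 the real split gave 2935, 3621, 4466 and 4454 probe sets and the highest other split 3668, 3327, 2046 and 3006. In total RNA that highest split set control mouse 1 with transgenic mice 1 and 2. Between fractions, with arrays taken as independent, 1 of 10 splits gave as many in control mice (14137, highest other 0) and 1 of 10 in transgenic mice (9594, highest other 0), and these too are too few. Over all 6 mice, 1 of 32 sign flips gave as many (17955, highest other 0), the smallest share that 32 flips can give. Chance is thus argued against for the difference between fractions, but not excluded.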

How the results depend on the processing

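The rescaled tail ratios and, for gene lists, the filters, scalings and omissions of mice were chosen only after the results were seen. With array weights 3901 probe sets passed in total RNA, 17186 in the tail ratio of transgenic mice, 6073 in its genotype difference, 1085 in the short-tail and 12569 in the long-tail fraction. Other splits of the mice gave up to 1561, 13213, 2347 and 14972 with such weights in the genotype comparisons, in the same order, and 1 array had a weight of 190. With 1 probe set per gene, and so fewer tested, 7240 passed in control and 2849 in transgenic mice. In transgenic mice the 60th percentile filter gave 4612 and quantile normalization again 4986. In the short-tail fraction the 60th percentile filter gave 5, each of quantile normalization again, normalization within each fraction and centring 2, and an adjusted p under 0.10 gave 6. With all 18 arrays in 1 model, which shares 1 spread over the preparations, 4677 passed in the long-tail fraction. Leaving out each mouse gave 0 to 13560 in the tail ratio of transgenic mice (0 without transgenic mouse 1 or 2, 13560 without control mouse 1), 0 to 2487 in its genotype difference and 0 to 2319 in the long-tail fraction (both highest without control mouse 2), and 0 to 359 in the short-tail fraction (359 without transgenic mouse 3, 10 without transgenic mouse 1). In control mice 13108 to 16944 passed. Where 0 passed in total RNA, 0 also passed under every setting but array weights. Except for fewer probe sets tested or fewer mice, the cause was not tested.

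Single genes that turned sign did not pass in either setting. Cpeb4 in total RNA read -0.0735 with quantile normalization again, -0.0743 within each fraction and -0.0969 to 0.197 without single mice. In the short-tail fraction it read -0.0651, -0.0726 and -0.136 to 0.126 in the same settings. In the genotype difference of the tail ratio Cpeb4 read -0.171 with array weights, -0.332 and -0.341 after rescaling to the same SD and slope, and -0.23 to 0.3 without single mice. In the long-tail fraction it read -0.206 with array weights and -0.267 to 0.306 without single mice. Cpeb1 read -0.0439 with array weights in total RNA, and -0.0186 to 0.401 without single mice in the tail ratio. Cpeb2 read -0.0916 to 0.272 without single mice in total RNA, 0.0291 with quantile normalization again and -0.553 to 0.122 without single mice in the tail ratio, and -0.181 with array weights and -0.225 to 0.244 without single mice in the long-tail fraction. Cpeb3 in the short-tail fraction read 0.0317 with array weights and -0.123 to 0.0249 without single mice. The cause was not tested.

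Of the gene lists, 0 passed with an estimated correlation and 0 with fry in total RNA and in the genotype difference of the tail ratio. In the latter 3 of the 8 lists still passed after rescaling to the same SD or slope. The 5 lists that passed at each rescaling included endothelial and mural markers (-0.157 and -0.161, adjusted p = 0.007 and 0.0058) and meningeal genes (-0.228 and -0.253, adjusted p = 0.0048 and 0.0035), which did not pass as measured (-0.0761 and -0.0697, adjusted p = 0.52 for each). Without single mice 3 to 8 passed (3 without control mouse 3). For autism-associated genes the median was -0.132 with an estimated correlation and with fry (adjusted p = 0.72 and 0.5), -0.109 without a filter, 0.0179 and 0.0314 after rescaling to the same SD and slope, and -0.185 to -0.0662 without single mice (adjusted p from 0.00016 to 0.81 over all alternatives). The same rescalings gave 0.00307 and 0.00576 for the glutamatergic postsynapse and 0.00982 and 0.0402 for chromatin regulators. In the tail ratio of transgenic mice, autism-associated genes read -0.0123 with all probe sets averaged, -0.0115 when normalized within each fraction and -0.0544 when centred, and the postsynapse -0.0101 and -0.046 in the latter settings. Chromatin regulators there read 0.22 with quantile normalization again and -0.049 to 0.0264 without single mice. In total RNA autism-associated genes read 0.0044 when centred and -0.0265 to 0.0192 without single mice, and presynaptic genes -0.117 to 0.000325. In the short-tail fraction autism-associated genes read -0.00016 with fry, -0.000629 without a filter, 0.000342 with the 60th percentile filter, 0.0106 when centred and -0.0213 to 0.0395 without single mice, and voltage-gated channels -0.111 to 0.0577. In the long-tail fraction chromatin regulators read -0.169 to 0.00411. The cause was not tested. The ribosomal, oxidative phosphorylation and proteasome lists kept their direction in the genotype difference of the tail ratio under every setting run, and passed under all but the estimated correlation and fry.

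Replicate numbers were not taken to pair the genotypes. Deviations of mice with the same number correlated at -0.31 to 0.36 in the tail ratio. These values cannot show whether such mice were paired, since short-tail and long-tail arrays of the same control mouse correlated at only -0.07 to 0.16. With a replicate block 0 probe sets passed in limma in total RNA, the genotype difference of the tail ratio, the short-tail and the long-tail fraction (lowest adjusted p = 0.293, 0.245, 0.183 and 0.233; 3774, 4432, 4573 and 4954 at an unadjusted p under 0.05). Without that block the latter counts were 2935, 3621, 4466 and 4454. With no replicate block between the fractions of a mouse 16291 passed in control mice, 7789 in transgenic mice and 0 in their difference (lowest adjusted p = 0.51; 2570 at an unadjusted p under 0.05). Ratios of the long-tail fraction to total RNA and of total RNA to the short-tail fraction gave 0 (lowest adjusted p = 0.692 and 0.855; 1859 and 1437 at an unadjusted p under 0.05). The planned test of cytoplasmic polyadenylation elements was not run. Signal over background limits what can be read, since 14640 to 31233 of 45037 probe sets per array stood above the highest nonspecific control.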

Other observations

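The values here were picked out, and the tests on them chosen, only after the results were seen. Replication-dependent histone mRNAs, most of which carry no poly(A) tail, did not pass as a list in the tail ratio of control or transgenic mice (camera adjusted p = 0.75 and 0.68). In control mice 6 of 12 measured ones lay toward short tails and 1 toward long tails, where 4772 and 2457 of all 11974 genes did, and in transgenic mice 3 and 0. H2bc4 read -2.56 ± 0.42 in control and -1.50 ± 0.45 in transgenic mice, H2bc22 -2.82 ± 1.1 and -1.38 ± 0.22, and H1f2 -2.81 ± 1.2 and -1.04 ± 0.57 (SD, n = 3). These control values are not exact, as H2bc4 stood above the highest nonspecific control on 1 of 3 control long-tail arrays and H2bc22 and H1f2 on 2. The median signal of the 12 histone mRNAs was lower in both fractions than in total RNA. In control mice it was 8.74 ± 0.11 in total RNA, 7.90 ± 0.16 in the short-tail and 6.88 ± 0.12 in the long-tail fraction. In transgenic mice it was 8.83 ± 0.14, 8.01 ± 0.29 and 7.59 ± 0.14.

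Nuclear long noncoding RNAs were divided in control mice, with 6 of 14 toward the long-tail and 3 toward the short-tail fraction, and did not pass as a list (camera adjusted p = 0.24). Their median of 0.19 ranked at percentile 98.9 of random lists of the same expression, above the range of -0.80 to 0.12 that held most of those lists. Whether these RNAs carry tails of that length was not measured. Xist read 0.74 ± 0.25 and Malat1 0.65 ± 0.09, whereas Gas5, a host of small nucleolar RNAs, read -1.84 ± 0.47, with 2 of 3 control long-tail arrays above the highest nonspecific control, and Pantr1 -1.92 ± 0.37.

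Probe sets without an entry in the annotation leaned toward long tails and those of 1 gene toward short tails. Their median tail ratios were 0.31 and -0.18 in control mice and 0.15 and -0.18 in transgenic mice. Of 7468 without an entry 3412 passed toward long and 1858 toward short tails in control mice, against 3962 and 7528 of 19143 with 1 gene. The difference between both kinds was 0.59, 0.33 and 0.42 in control and 0.36, 0.40 and 0.20 in transgenic mice. Its smallest value over 5 bins of expression ran from -0.0012 to 0.067.

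Probe sets of 1 gene could pass in opposite directions. Of 3871 genes with several probe sets and at least 1 passing in control mice, 464 (12.0%) had probe sets passing toward both fractions, and of 2221 in transgenic mice 96 (4.32%) did. The tail ratio of such a gene therefore depends on the probe set that represents it.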
